A study of Bos taurus and Mus musculus with 16 samples.

How the data were processed

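Polyadenylated RNA of mouse morulae and bovine blastocysts was primed with oligo(dT) and made into libraries by Smart-seq2, per the labels' protocols. The submitters' processing notes name Trimmomatic, HISAT2, featureCounts and DESeq2, with no versions, and the genome builds mm10 and ARS-UCD1.2. Gene annotation, strand setting and the treatment of reads with several matches were not given in the sources used here, so values of near-identical copies and of overlapping or antisense genes are uncertain. The deposited signal values, one table per species, are gene-level read counts that the authors divided by a DESeq2 size factor per sample, per the file headers and the values. The same tables hold the authors' DESeq2 log2 fold changes with standard errors, the authors' DESeq2 test statistic, which has no fixed range and was treated as a score, and the authors' p-values and adjusted p-values, per the file headers. These columns of the authors' own comparison were only counted and quoted, always under the name of the authors' deposited table, and the score was not used.

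There were 16655 genes and 4 samples in the mouse table, and 14852 genes and 12 samples in the bovine one. No gene in the mouse table had fewer than 11 reads over all samples and none in the bovine table fewer than 16. In each sample every value was a whole multiple of the value of 1 read, so whole reads were recovered for 100% of values at a tolerance of 0.05 reads. The recovered totals per sample are the depths given in the results, and 3 reads correspond to 2.13 to 3.79 normalized reads in the mouse samples and to 1.71 to 5.56 in the bovine samples, a limit that covers counting error only. Gene names were used as given. Of the names, 19 in mouse and 20 in bovine have the form of calendar dates, which some spreadsheet programs give to gene symbols, and none of these is named here. Of the mouse names, 89.1% matched the GENCODE M21 annotation of GRCm38 (mm10), which gave coordinates and transcript lengths. Of the bovine names, 93.6% matched a gene table of the assembly ARS-UCD2.0, which is not the authors' build and was used only for gene types, chromosomes and neighbours.

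Groups and replicate numbers were taken from the sample titles. The 2 tables were normalized separately, so every test was made within a table. Before the data were examined, the test, the gene lists, the rule for named genes and the alternatives were fixed. Each gene with a mean of at least 10 normalized reads over the samples of its table (11386 in mouse, 8884 in bovine) was tested on log2(value + 1) with limma 3.58.1 (R 4.3.3, trend on mean expression, edited minus control, two-sided), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A fold change on this scale understates the change of low genes. Every adjusted p in the text comes from limma unless another tool is named. The design had assumed normalized values, which is what the tables hold.

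The 22 gene lists covered trophectoderm markers, inner cell mass and epiblast markers, primitive endoderm markers, Hippo pathway components, YAP-TEAD target genes of cultured cells, blastocoel and junction genes, glycolysis, nuclear and mitochondrial oxidative phosphorylation, ribosomal proteins, p53 target genes, the integrated stress response, antioxidant response, cholesterol synthesis, proliferation, DNA methylation and imprinting, interferon-stimulated genes, oocyte and maternal transcripts and cleavage-stage transcripts. Markers of cells that a sample could hold besides the embryo were listed too, for cumulus and granulosa cells, blood cells and spermatozoa. Lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01 between genes and adjusted over the lists of a species. Members were counted by their adjusted p over all genes and by a p adjusted over the list alone. Named genes were the edited gene, 25 core lineage and Hippo genes whether or not they passed, up to 4 members per list with the largest change among those that passed, and the 8 genes that rose and the 8 that fell with the largest change among those that passed, with a mean of at least 100, a symbol that is not a predicted locus and no overlap between groups. Where fewer than 10 genes passed, as in bovine, the last part of the rule took genes with an unadjusted p under 0.01 instead. Some of the mouse genes that the rule takes are given only within counts or are not reported here. A gene named outside the rule is said to have been chosen after its values were seen, except list members that are given to describe a list. The difference between species of a core gene was the difference of both log2 fold changes over the root of the summed squared limma standard errors, with Satterthwaite degrees of freedom. Shared calls were tested with Fisher's exact test over genes with the same symbol.

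Alternatives fixed in advance were a pseudocount of 0.5 or 5, no filter on low values or a mean of at least 50, TMM factors, scaling to the same total, the replicate number as a block, robust limma, sample weights, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, an estimated correlation in camera, an interaction term over both tables, and leaving out each library in turn. Where that leaves 1 sample in a mouse group, the lone sample is assumed to vary like the other group. The spread then comes from the other pair alone, so a call lost in such a fit need not rest on the library left out. On the recovered reads edgeR called 1670 mouse genes and 1 bovine gene, and DESeq2 called 1354 and 5, where 442 mouse and 7 bovine genes had no adjusted p from DESeq2 and were left so. Scaling to the same total without the most abundant feature, and removing a loess trend over transcript length from each mouse sample, were chosen after seeing the data. Transcript length was that of the longest annotated transcript, known for 93.9% of tested mouse genes.

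No samples of a group agreed within sampling noise, since chi-square per degree of freedom ranged from 6.86 to 49.9 over pairs of one group, so each sample counted once. The fits were tested on simulated reads drawn from the means and depths of the real samples. For mouse (11140 genes, of which 99 were changed 2-fold and 99 changed 4-fold) limma called 41.4% and 78.8% of these. For bovine (8713 genes, with 98 and 100 changed) it called 53.1% and 94%. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and plots drawn with matplotlib 3.10.9. The guide target sites and the edited alleles were not analysed here, so the share of edited copies per embryo is not part of the results.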

Results

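RNA was sequenced from 16 samples of preimplantation embryos of 2 species. Zygotes were injected with mRNA of BE3, a cytosine base editor that joins a Cas9 nickase to a cytidine deaminase, either alone (control) or together with single guide RNAs against Tead4 in mouse and TEAD4 in cattle (edited). The controls received no guide RNA, so effects of the guide RNAs other than loss of TEAD4 cannot be told apart from that loss. Mouse embryos were collected as morulae on day 3.25, with 2 control and 2 edited samples, and bovine embryos as blastocysts on day 7.0, with 6 control and 6 edited samples. The mouse libraries held 4187826 and 3642907 reads assigned to genes in the control group and 4386305 and 6109425 in the edited group. The bovine libraries were shallower, with 934078 to 2501592 reads in the control group and 817329 to 2259064 in the edited group. In the bovine libraries the 18S ribosomal RNA gene RN18S1 took 20.7% ± 9.11 (SD, n = 6) of the reads in control and 12.5% ± 3.79 (SD, n = 6) in edited samples. In the mouse libraries the most abundant feature, LOC101056014, took 2.42% and 3.30% of the reads in control and 7.20% and 4.73% in edited samples. How many embryos made up a sample, and whether samples came from separate injections, was not given in the sources used here, so the p-values below measure only the spread between these samples, which may be technical.

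The first comparison asked which transcripts of the mouse morula differed after editing of Tead4, a DNA-binding factor that acts with the co-activators Yap1 and Wwtr1 (Taz) downstream of Hippo signalling. Tead4 (chromosome 6, 128224288 to 128300823, minus strand, GRCm38) itself stood at 458 and 519 normalized reads in the control samples and at 57.2 and 76.5 in the edited samples. It fell to 13.7% of the control mean, a log2 fold change of -2.86 ± 0.25 (SE, n = 2 per group) with an adjusted p of 5.37e-09 from limma. Of 22 tested markers of the trophectoderm, the outer epithelium that founds the placenta, 11 fell, Tead4 itself among them, and 2 rose. Gata3 (chromosome 2, 9857078 to 9890034, minus strand), a transcription factor of that lineage, went from 1013 ± 0.515 to 222 ± 49.7 normalized reads (mean ± SD), and the keratin gene Krt18 (chromosome 15, 102028180 to 102032027, plus strand) from 2079 ± 617 to 164 ± 106. Pou5f1 (chromosome 17, 35506018 to 35510772, plus strand), a pluripotency factor, rose from 390.3 ± 65.2 to 1031 ± 143, a log2 fold change of 1.40 ± 0.19. In what follows, each mouse gene printed with a standard error also passed in every fit that left out 1 library and could test it, except where an exception is stated.

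In the mouse comparison limma called 1742 of 11386 tested genes at a Benjamini-Hochberg adjusted p under 0.05, of which 788 were higher and 954 lower in edited morulae. Of these, 485 rose and 403 fell by at least 2-fold. The authors' deposited table listed 1319 genes under the same threshold, 564 higher and 755 lower. The count was 580 without control library 1 and 601 without control library 2, and without edited library 2 the number of lower genes was 1514. Scaling every sample to the same total put the median log2 fold change of all genes at 0.12 and turned the split to 1111 higher and 682 lower (62.0% higher, against 45.2%), and leaving LOC101056014 out of that total gave 1277 higher and 610 lower.

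Of the 22 tested trophectoderm markers, which include Tead4, 11 fell and 2 rose over all genes. When adjusted over the list alone, 13 fell and 3 rose. The list median was -0.88 (camera, preset correlation, adjusted p = 2.14e-08), with adjusted p = 0.402 with an estimated correlation. With so few mouse samples hardly any list could pass with an estimated correlation. Id2, a dominant-negative partner of helix-loop-helix factors, had a log2 fold change of -4.17 ± 0.36, the prostaglandin E synthase gene Ptges one of -3.97 ± 0.25, and the endocytic adaptor gene Dab2 one of -3.73 ± 0.21. Krt18 had a log2 fold change of -3.79 ± 0.28 (adjusted p = 0.0553 with robust limma), Gata3 of -2.20 ± 0.20 and Krt8 of -1.74 ± 0.18. Cdx2 (chromosome 5, 147300805 to 147307270, minus strand), the caudal-type homeobox factor of the trophectoderm, went from 56.5 to 12.8 normalized reads, a log2 fold change of -2.06 ± 0.46 (adjusted p = 0.00303). Its call was lost without control library 1 and without control library 2, where the higher adjusted p was 0.0682. The members that rose were Hand1 (1.68), a factor of trophoblast giant cells, and the glucose transporter gene Slc2a1 (0.79). Tfap2a had a log2 fold change of -2.12 and missed the threshold (adjusted p = 0.0517), although it passed without edited library 1, at -2.52. Eomes (0.46) and Tfap2c (0.18) did not pass either, and Gata2 and Elf5 were below the filter on low values.

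Among 22 inner cell mass and epiblast markers, 8 rose and 1 fell over all genes, and 10 rose and 4 fell when adjusted over the list alone. The list median was 0.68 (camera adjusted p = 0.0107), with adjusted p = 0.402 with an estimated correlation. Without control library 2 the median was 0.29 and 5 rose, and without edited library 2, 6 fell. Besides Pou5f1, the Nodal co-receptor gene Tdgf1 rose by 1.35 ± 0.22 and the Krüppel-like factor gene Klf2 by 1.33 ± 0.25. Klf17 rose by 1.84 ± 0.40, a call that was lost without edited library 1 (adjusted p = 0.0653). Dppa5a was the member that fell (-0.73). Sox2 had a log2 fold change of 1.04 ± 0.44 and did not pass (adjusted p = 0.117). Nanog stood at 1618 and 1918 normalized reads in control and at 738 and 1884 in edited samples and did not pass (adjusted p = 0.122). Its log2 fold change was -1.25 without edited library 2 and 0.097 without edited library 1. The 16 primitive endoderm markers moved in both directions, 3 up and 3 down over all genes, and 4 up and 3 down when adjusted over the list alone. Their median was 0.13, while their mean (-0.03) and the camera test pointed down (adjusted p = 0.885). Without edited library 1 that test passed, pointing down (adjusted p = 0.0224), at a median of 0.37, and the median turned to -0.20 without control library 2 and -0.22 without edited library 2. Lrp2 (chromosome 2, 69424340 to 69586065, minus strand), which encodes the endocytic receptor megalin, went from 1985 ± 249 to 23.3 ± 4.84 normalized reads, a log2 fold change of -6.36 ± 0.24 (adjusted p = 9.85e-17). Gata4 rose from 7.22 to 39.7 normalized reads, a log2 fold change of 2.34 ± 0.56. The collagen chaperone gene Serpinh1 rose by 3.64 ± 0.75, but its edited samples stood at 273 and 17.7 normalized reads, its value was 5.57 without edited library 2, and it did not pass with robust limma (adjusted p = 0.194). Gata6 (-0.33) and Pdgfra (0.13) did not pass, nor did Sox17, whose sign differed between limma (-0.78), edgeR (0.45) and the fit without edited library 1 (1.32).

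**Figure D1:**
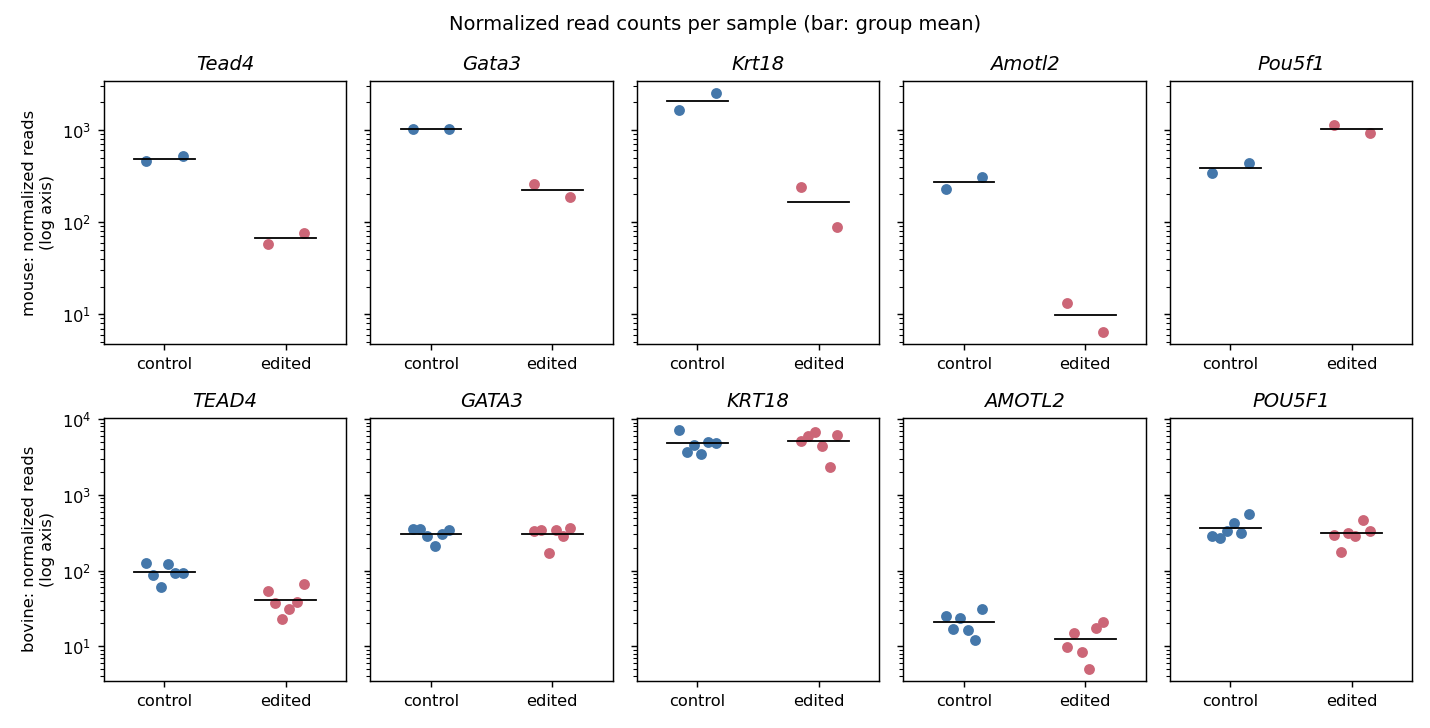
Normalized reads of TEAD4, GATA3, KRT18, AMOTL2 and POU5F1 in each mouse sample (upper panels) and bovine sample (lower panels), on a log axis with 1 point per sample and a bar at the group mean. In mouse the edited samples lie below the control samples for Tead4 (57.2 and 76.5 against 458 and 519), Gata3, Krt18 and Amotl2 and above them for Pou5f1, whereas in bovine the groups overlap for each of these genes.

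The 10 tested target genes of YAP and TEAD proteins, taken from work on cultured cells, held 5 members that fell and 0 that rose over all genes (limma), and 6 and 0 when adjusted over the list alone. Their median was -0.77 (camera adjusted p = 0.00274), with adjusted p = 0.458 with an estimated correlation. Over all genes 3 fell without control library 1 and 2 without control library 2, and the median was -0.50 without edited library 1. Amotl2 (chromosome 9, 102716672 to 102733418, plus strand), which encodes an angiomotin family scaffold, went from 269.6 ± 58.8 to 9.86 ± 4.93 normalized reads, a log2 fold change of -4.70 ± 0.39. Cyr61 (Ccn1) fell by 1.63 ± 0.33 on the log2 scale. Lats2, a Hippo kinase gene, fell by 1.47 ± 0.31, a call lost without control library 2 (adjusted p = 0.110). Ctgf (Ccn2) fell by 1.17 ± 0.36 (adjusted p = 0.0267), a call that stood only without edited library 2 among the fits that left out 1 library, with adjusted p up to 0.254 in the others, and which was lost with edgeR (0.0512) and DESeq2 (0.0991). Among 28 Hippo pathway components, 4 fell and 2 rose over all genes, and 5 fell and 4 rose when adjusted over the list alone, with a median of 0.02, a mean of -0.19 and a camera test pointing down (adjusted p = 0.69). Without control library 1, 2 of them fell and 0 rose, and without control library 2, 2 fell and 1 rose (limma), and the median turned to -0.07 without edited library 1. Vgll3 (-3.32 ± 0.80) and Vgll4 (-1.82 ± 0.35), which encode TEAD-binding cofactors, and the LIM protein gene Ajuba (-1.69 ± 0.35) fell. Wwtr1 rose by 0.72 ± 0.22 (adjusted p = 0.0226), a call lost without control library 1 and without edited library 1, with adjusted p up to 0.465. Yap1 (0.14), Tead1 (-0.46) and Tead2 (0.36) did not pass, and Tead3 was below the filter. Of 23 genes for junctions and the blastocoel, the fluid-filled cavity of the blastocyst, 7 fell and 2 rose over all genes, and 8 fell and 3 rose when adjusted over the list alone, with a median of -0.42 (camera adjusted p = 0.103). Without control library 1 this list passed (adjusted p = 0.0302), with 3 members that fell, and without control library 2 its median was -0.20, with 2 that fell, and -0.20 without edited library 1. The tight junction gene Tjp3 fell by 2.20 ± 0.43 on the log2 scale, and plakoglobin (Jup) rose by 1.23 ± 0.23.

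All 63 of the 80 ribosomal protein genes that passed over all genes fell, as did 73 when adjusted over the list alone. Their median was -0.60 (camera adjusted p = 8.13e-28), with adjusted p = 0.402 with an estimated correlation. Without control library 1, 11 of them fell over all genes, and 18 did without control library 2. Rpl36a fell by 1.10 ± 0.18 on the log2 scale and Rps28 by 1.03 ± 0.16. Of 92 nuclear genes of oxidative phosphorylation, 46 fell and 0 rose over all genes (limma), and 64 fell and 1 rose when adjusted over the list alone, with a median of -0.58 (camera adjusted p = 5.37e-17) and adjusted p = 0.402 with an estimated correlation. In this list 5 fell over all genes without control library 1 and 17 without control library 2. Cox5a, a subunit gene of cytochrome c oxidase, went from 3087 ± 232 to 1307 ± 6.71 normalized reads, a log2 fold change of -1.24 ± 0.16. Both lists consist of short transcripts, with median lengths of 1054 and 1200 nucleotides, and when all tested genes were put into 10 groups by length, the shortest group had a median log2 fold change of -0.47, against 0.05 to 0.09 in the longest 7 groups. With the length trend of each sample removed, an alternative chosen after seeing the data, 25 ribosomal protein genes and 18 oxidative phosphorylation genes fell, with medians of -0.28 and -0.32. The 13 mitochondrially encoded genes had a median of -0.25 (camera adjusted p = 0.176), or -0.14 without edited library 1 and -0.37 without edited library 2, and 1, ND6, fell over all genes and over the list alone, a call lost without control library 2 (adjusted p = 0.284). Of 14 glycolysis genes, 2 rose and 2 fell over all genes, and 3 rose and 2 fell when adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.606), which was 0.08 without control library 1 and -0.08 without edited library 2. Its hexokinase genes moved apart, with Hk1 at 1.61 ± 0.26 and Hk2 at -1.31 ± 0.22.

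**Figure D2:**
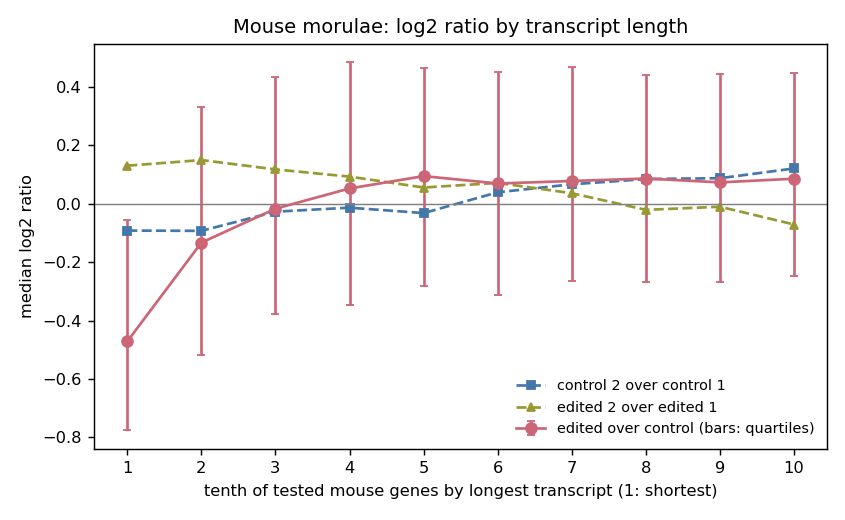
Median log2 ratio of mouse genes in 10 groups by length of the longest transcript, from the shortest to the longest, for edited over control (bars are quartiles over genes), for control 2 over control 1 and for edited 2 over edited 1. Edited over control starts at -0.47 in the shortest group, where the ratios within the groups are -0.09 and 0.13.

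Of 24 p53 target genes, 10 rose and 0 fell over all genes (limma), and 12 and 0 when adjusted over the list alone, with a median of 0.47 (camera adjusted p = 3.23e-05) and adjusted p = 0.402 with an estimated correlation. Without control libraries 1 and 2 the members that rose over all genes numbered 4 and 6. The stress sensor gene Sesn2 rose by 1.71 ± 0.26 and the polo-like kinase gene Plk2 by 1.40 ± 0.23. Of 17 genes of the integrated stress response, 5 rose and 1 fell over all genes, and 5 and 2 when adjusted over the list alone. Their median was 0.34 (camera adjusted p = 0.0623, and adjusted p = 0.402 with an estimated correlation). The list passed without control library 1 (adjusted p = 0.0223) and without edited library 2 (0.00835), while its rising members numbered 2 and 1 without control libraries 1 and 2 and 3 without edited library 1, and its median was 0.12 without control library 2 and 0.14 without edited library 1. Ddit4, an inhibitor of mTORC1 signalling, rose by 3.19 ± 0.43, with 1270.0 and 213 normalized reads in the edited samples against 46.9 and 67.0 in the controls. Its value was 1.90 without edited library 1, and it did not pass with robust limma (adjusted p = 0.261). Among 21 antioxidant genes, 5 fell and 2 rose, both over all genes and when adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.19). Without edited library 2 the antioxidant list passed (adjusted p = 0.00835), with 9 that fell, against 2 without either control library, and without edited library 1 its median turned to 0.17. The heme oxygenase gene Hmox1 rose by 1.85 ± 0.27 and the peroxiredoxin gene Prdx6 fell by 1.03 ± 0.17 on the log2 scale. Of 23 cholesterol synthesis genes, 6 fell and 1 rose over all genes, and 9 fell and 1 rose when adjusted over the list alone. Their median was -0.55 (camera adjusted p = 0.000197), with adjusted p = 0.604 with an estimated correlation, and the phosphomevalonate kinase gene Pmvk had the largest fall, -1.94 ± 0.28. The cholesterol list passed in each fit that left out 1 library, but its median was -0.85 without control library 1 (3 fell), -0.23 without control library 2 (1 fell) and -0.32 without edited library 1, and 12 fell without edited library 2. The 30 proliferation genes had 5 members that rose and 1 that fell, and 6 and 3 when adjusted over the list alone, with a median of 0.20 (camera adjusted p = 0.176), and without control library 1 or control library 2 none passed over all genes (limma). Of 20 genes of DNA methylation and imprinting, 1 fell over all genes and over the list alone, with a median of 0.08 (camera adjusted p = 0.83), which turned to -0.18 without control library 1 and -0.12 without edited library 2. It was Dnmt3l, a cofactor of DNA methyltransferases, at 49.9% of its control mean, whose call was lost without control library 1 (adjusted p = 0.0869).

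Of 16 transcripts typical of the 2-cell and cleavage stages, 11 rose and 0 fell over all genes (limma), and 13 and 0 when adjusted over the list alone. Their median was 1.81 (camera adjusted p = 4.25e-09), with adjusted p = 0.402 with an estimated correlation. Without control libraries 1 and 2 the members that rose numbered 7 and 6. Gm5662 rose from 27.9 ± 12.7 to 249 ± 148 normalized reads, a log2 fold change of 3.05 ± 0.38, and Usp17la, a multicopy deubiquitinase gene, rose by 4.62 ± 0.73 from 1.19 normalized reads. Usp17l and Tdpoz genes have near-identical copies, so values of single members are uncertain, and Klf17 stands in this list and among the epiblast markers. The 8 oocyte and maternal transcripts went both ways, 1 up and 2 down over all genes and when adjusted over the list alone, with a median of 0.58 (camera adjusted p = 0.892), or 0.20 without edited library 2. Of these, Ooep (-1.88 ± 0.31) and Dppa3 (-1.03 ± 0.16) fell. Of 6 markers of cumulus and granulosa cells, the somatic cells around the oocyte, 2 rose and 0 fell over all genes (limma), and 3 and 0 when adjusted over the list alone, with a median of 0.63 (camera adjusted p = 0.0466) and adjusted p = 0.49 with an estimated correlation. That list lost its call without control library 2 (adjusted p = 0.177), without edited library 1 (0.166) and with the length trend removed (0.0706). The 2 members were Vim (2.15) and Serpine2 (0.79), which embryos can also express. Vim stood at 71.5 and 32.6 normalized reads in the edited samples, and its call was lost without edited library 1 (adjusted p = 0.147), while that of Serpine2 was lost without control library 1 (0.12) and control library 2 (0.259). Lists with fewer than 5 tested members were not tested as sets: Stat2 rose (1.26) among 4 interferon-stimulated genes, a call that stood only without edited library 2 among the fits that left out 1 library, and of 2 blood cell markers and 1 sperm transcript none passed.

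Outside the lists, the genes with a mean of at least 100 normalized reads and the largest changes included Socs3 (2.94 ± 0.40), an inhibitor of cytokine signalling, and the annexin gene Anxa8 (2.31 ± 0.36) among those that rose. Anxa8 did not pass with DESeq2 (adjusted p = 0.0504), and its value ran from 1.52 without control library 2 to 3.10 without control library 1. The splicing factor gene Sf3a2 (2.23 ± 0.27), the retinoic acid receptor gene Rarg (2.22 ± 0.34), Baiap2 (2.21 ± 0.24) and the chromatin remodeller gene Srcap (2.09 ± 0.31) also rose. S100a11, a calcium-binding protein gene, fell by 4.04 ± 0.28 on the log2 scale, and Trp53bp2, which encodes a p53-binding protein, by 3.45 ± 0.29.

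The second comparison asked the same question of the bovine blastocyst. TEAD4 itself stood at 61.2 to 125 normalized reads in the 6 control samples and at 22.6 to 65.6 in the 6 edited samples, so that the groups overlapped by 1 sample on each side. Its mean went from 96.7 ± 23.4 to 41.2 ± 15.6 (SD, n = 6), a log2 fold change of -1.25 ± 0.25. Over all 8884 tested genes limma gave an adjusted p of 0.235, whereas DESeq2 on the recovered reads gave 0.0066, and an adjusted p of 0.0142 stood in the authors' deposited table. When adjusted over the list of trophectoderm markers alone, its p was 0.00138. The single gene that passed with limma was LOC101905257, a predicted protein-coding locus, which went from 401 ± 139 to 81.4 ± 34.4 normalized reads, a log2 fold change of -2.31 ± 0.27 (adjusted p = 0.000478), with all 6 edited samples below all 6 controls. It is outside the rule for named genes and was singled out after its values were seen.

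GATA3 had the same mean in both bovine groups, 306 ± 54.8 and 307 ± 71.3 normalized reads, a log2 fold change of -0.02 ± 0.20 with a 95% interval from -0.43 to 0.40. KRT18 (0.05 ± 0.24, interval from -0.44 to 0.55) and KRT8 (0.14 ± 0.23) did not pass, nor did POU5F1 (-0.25 ± 0.22) and SOX2 (-0.52 ± 0.34). AMOTL2 (-0.73 ± 0.35), CYR61 (-0.66 ± 0.49), CTGF (-0.29 ± 0.40) and YAP1 (-0.51 ± 0.19) had negative values that did not pass. NANOG (0.07 ± 1.05) varied so much between samples that its 95% interval ran from -2.13 to 2.26, and that of PDGFRA (0.02 ± 0.44) from -0.89 to 0.92. GATA6 (-0.17), TFAP2C (-0.35), GATA2 (-0.43), TEAD1 (-0.20), TEAD3 (-0.14) and WWTR1 (-0.06) did not pass either. CDX2 was below the filter on low values, with 1.46 to 19.9 normalized reads in control and 2.01 to 11.1 in edited samples. The rule for named genes also took CLIC1, a chloride channel gene (0.60 ± 0.16), and the linker histone gene HIST1H1C (-0.90 ± 0.18), whose groups did not overlap but which did not pass (adjusted p = 0.792 and 0.235 with limma).

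In bovine blastocysts limma thus called 1 gene, lower in edited samples, and 0 higher, with 522 genes at an unadjusted p under 0.05. edgeR on the recovered reads called 1 gene and DESeq2 called 5, which were LOC101905257, HIST1H1C, TEAD4, the G protein subunit gene GNB4 and the laminin gene LAMA1, all lower. The authors' deposited table listed 3 genes, all lower. On data simulated from these libraries, with 98 genes changed 2-fold and 100 changed 4-fold, limma called 53.1% and 94% of them. With so many changed genes a larger p passes the adjustment, so these shares are too high for data with few changed genes.

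No bovine list had a member that passed over all genes with limma; of the genes DESeq2 called, TEAD4 and LAMA1 are members. The 22 Hippo pathway components had a median of -0.23, with 18 lower (camera adjusted p = 0.00683), and adjusted p = 0.104 with an estimated correlation. Without control library 6 that median was -0.14. When adjusted over the list alone 1 of them, the kinase scaffold gene WWC2 (-0.64), fell. The 12 targets of YAP and TEAD proteins had a median of -0.33, with 11 lower (camera adjusted p = 0.00683), adjusted p = 0.104 with an estimated correlation, and 0 past the threshold when adjusted over the list alone (limma). The 18 p53 target genes had a median of -0.23 (camera adjusted p = 0.0296) and the 17 genes of the integrated stress response one of 0.36 (camera adjusted p = 0.0391), both with adjusted p = 0.47 with an estimated correlation. The p53 list lost its call without control library 5 or edited libraries 1, 2 or 5 (adjusted p from 0.064 to 0.122) and had a median of -0.11 without control library 6, and the stress list without control libraries 3, 4 or 5 or edited libraries 3, 4 or 5 (0.064 to 0.227). The 13 mitochondrially encoded genes (median -0.23) and the 76 ribosomal protein genes (median -0.08) passed at a camera adjusted p of 0.0448, with adjusted p = 0.795 with an estimated correlation for both. Scaling every sample to the same total, which put the median of all bovine genes at 0.13, turned the ribosomal median to 0.04 and ended both calls (adjusted p = 0.0632 and 0.453), and TMM factors ended them too (0.0567 and 0.071). The mitochondrial list also lost its call without control libraries 1, 3 or 4 or edited libraries 1, 5 or 6 (adjusted p from 0.052 to 0.559), and the ribosomal list without control libraries 1, 3, 4 or 5 or edited libraries 4 or 5 (0.0659 to 0.95).

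The other bovine lists did not pass with all libraries at the authors' scaling. The 21 trophectoderm markers had a median of 0.07 while the camera test pointed down (adjusted p = 0.664), and 1 of them, TEAD4, passed when adjusted over the list alone. The 15 inner cell mass and epiblast markers had a median of -0.06 while the test pointed up (adjusted p = 0.751). The 16 primitive endoderm markers had a median of 0.02 while the test pointed down (adjusted p = 0.491), and LAMA1 (-1.89 ± 0.39) passed when adjusted over the list alone. Medians were 0.07 for 92 nuclear oxidative phosphorylation genes (adjusted p = 0.0909), 0.12 for 16 glycolysis genes (0.491), -0.07 for 23 junction and blastocoel genes (0.715) and 0.05 for 22 cholesterol synthesis genes (0.664). They were 0.20 for 18 antioxidant genes (adjusted p = 0.236), 0.13 for 29 proliferation genes (0.105), -0.08 for 13 genes of DNA methylation and imprinting (0.715) and 0.14 for 5 interferon-stimulated genes (0.715). The 5 oocyte and maternal transcripts (median -0.04, adjusted p = 0.596) and the 5 cleavage-stage transcripts (0.13, adjusted p = 0.491) did not pass either. Nuclear oxidative phosphorylation genes passed, upward, without control libraries 1 or 4 or edited library 4 and with the same total per sample (adjusted p from 0.00344 to 0.0409), and proliferation genes without control libraries 4 or 5 or edited library 4 (0.012 to 0.045). The medians of the trophectoderm, inner cell mass, primitive endoderm, junction, cholesterol, proliferation, DNA methylation and oocyte lists changed sign in at least 1 of the fits that left out 1 library. No member of these lists other than TEAD4 and LAMA1 passed when adjusted over its list alone. Of 4 tested cumulus markers, GATM (-1.93), COL1A2 (-1.05), HSD3B1 (-1.04) and SERPINE2 (0.28), none passed, nor did the 1 tested sperm transcript, and no blood cell marker reached the filter.

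**Figure D3:**
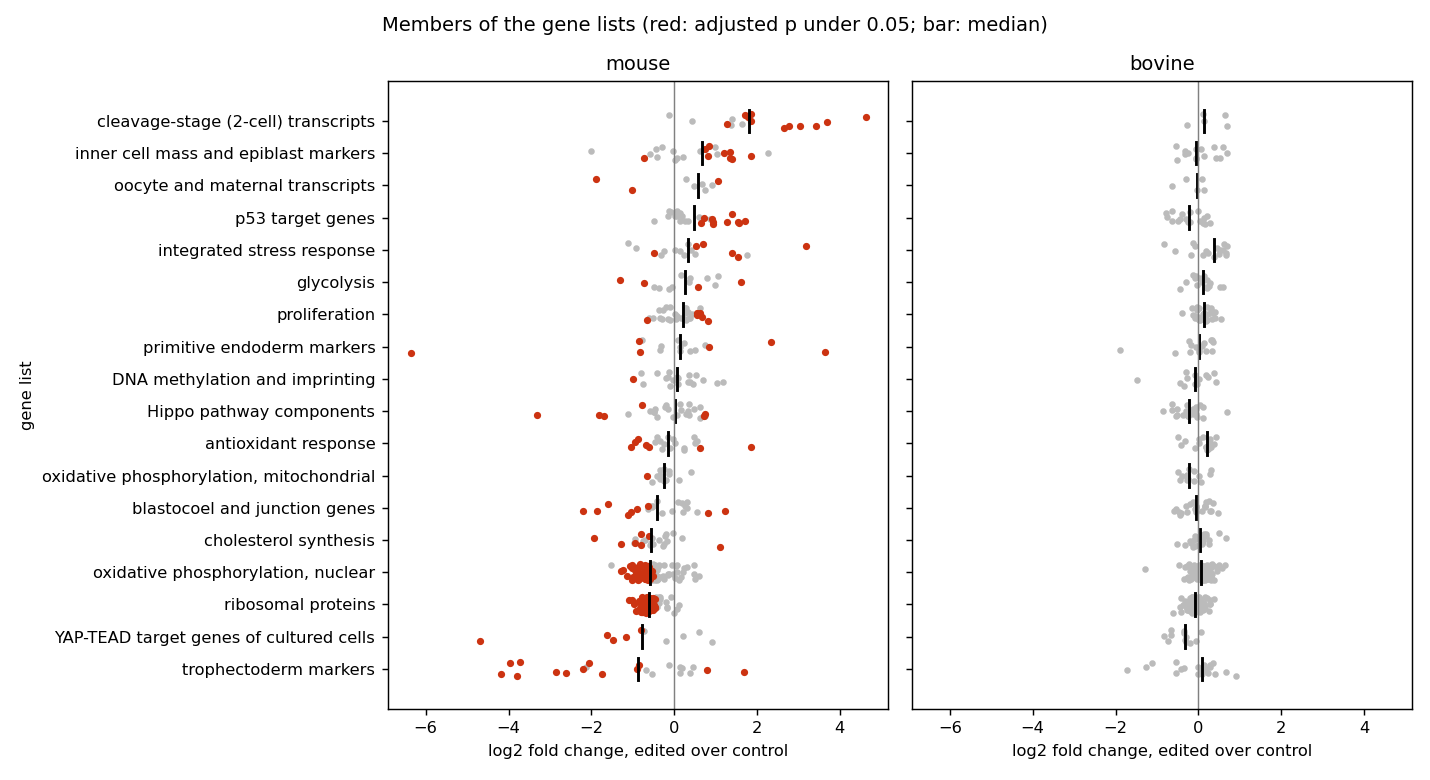
Log2 fold change, edited over control, of each tested member of the gene lists in mouse (left) and bovine (right), with 1 point per gene, red where the adjusted p over all genes was under 0.05 and a bar at the list median. In mouse the medians run from -0.88 (trophectoderm markers) to 1.81 (cleavage-stage transcripts), and in bovine no member is red.

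The third comparison set the effects of the 2 species side by side for the 16 core genes tested in both. The species differ in stage as well, since all mouse samples are morulae and all bovine samples blastocysts. The difference of the log2 fold changes, bovine minus mouse, passed for 8 genes (limma standard errors, Satterthwaite degrees of freedom, Benjamini-Hochberg). It was 3.97 ± 0.52 for AMOTL2, 3.84 ± 0.37 for KRT18, 2.18 ± 0.28 for GATA3 and 1.89 ± 0.29 for KRT8, which had all fallen in mouse. It was 1.61 ± 0.35 for TEAD4 itself (adjusted p = 9.37e-05). For POU5F1 it was -1.65 ± 0.29 (adjusted p = 4.61e-06), for SOX2 -1.56 ± 0.56 (adjusted p = 0.0178) and for WWTR1 -0.79 ± 0.29 (adjusted p = 0.0197). With an interaction term in 1 fit over both tables, SOX2 (adjusted p = 0.059) and WWTR1 (0.107) no longer passed. WWTR1 also lost its call without mouse control library 1 (adjusted p = 0.258) and mouse edited library 1 (0.121), and SOX2 without mouse control library 2 (0.0552). The difference did not pass for YAP1 (-0.65 ± 0.30), TFAP2C (-0.53 ± 0.25), CYR61 (0.97 ± 0.58), CTGF (0.88 ± 0.54), NANOG, GATA6, PDGFRA and TEAD1. Without mouse edited library 2 it passed for YAP1, TFAP2C, CYR61 and CTGF (adjusted p from 0.00332 to 0.0262). It also passed for YAP1 without bovine control library 5 or edited libraries 2 or 3, for TFAP2C without bovine control library 5, and for CYR61 without bovine control library 1 (0.0354 to 0.0482). With all libraries it passed for YAP1 and TFAP2C with sample weights (adjusted p = 0.0435 and 0.0492) and with the same total without the most abundant feature (0.0106 and 0.00942).

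**Figure D4:**
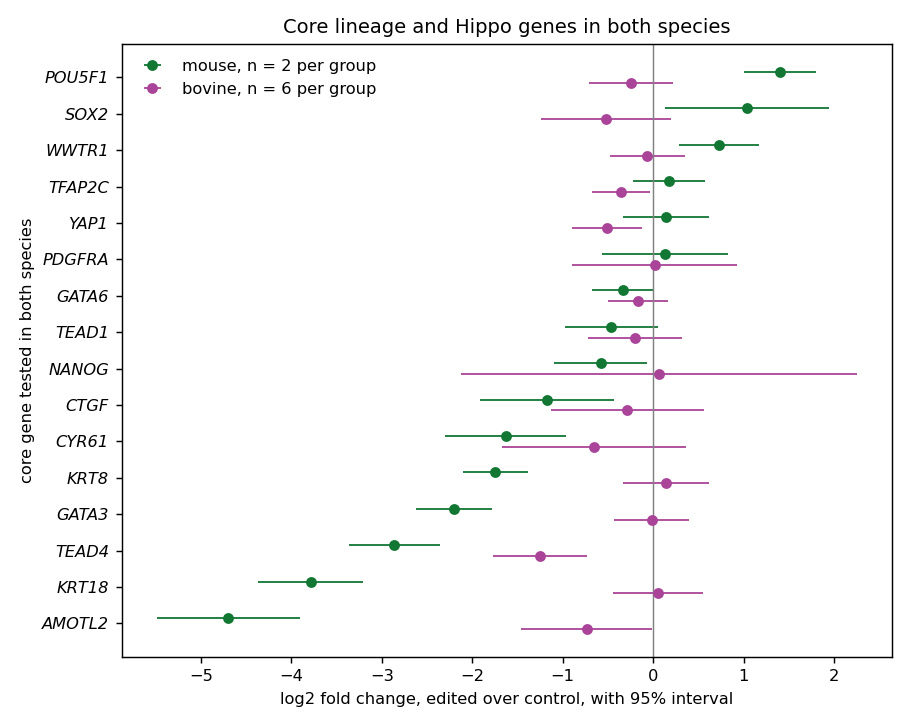
Log2 fold change, edited over control, with its 95% interval for the 16 core genes tested in both species, green for mouse morulae (n = 2 per group) and purple for bovine blastocysts (n = 6 per group). The intervals of KRT18, GATA3, KRT8, AMOTL2, TEAD4 and POU5F1 are apart between the species, with KRT18 at -3.79 in mouse and 0.05 in bovine.

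Across the 7063 genes with the same symbol tested in both tables, 456 rose and 656 fell in mouse and 0 passed in bovine with limma or edgeR, so that 0 calls were shared, where 522 bovine genes in all had an unadjusted p under 0.05. With DESeq2, 1 gene, TEAD4, fell in both (Fisher's exact test, two-sided, p = 0.147). The 656 genes that fell in mouse had a median log2 fold change of -0.83 there and of 0.02 in bovine. Of the 1112 genes that changed in mouse, 533 (47.9%) had the same sign in bovine. Across genes, which are not independent replicates, the fold changes of the 2 species had a Pearson correlation of 0.0030 and a Spearman correlation of -0.010.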

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

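The comparison of species was planned, and the prediction for the count of other splits of the bovine libraries was written before its result. The tests of library spread and of a proportional response were chosen only after the results were seen. The effect of editing differed between the species, by the test of the difference itself, for 8 of the 16 core genes. Bovine minus mouse, the difference of log2 fold changes was 2.18 for GATA3, 1.89 for KRT8, 3.84 for KRT18, 3.97 for AMOTL2 and 1.61 for TEAD4, and it was -1.65 for POU5F1, -1.56 for SOX2 and -0.79 for WWTR1. The last 2 lost their calls in fits without 1 mouse library. The difference for WWTR1 was then -0.47 without control library 1 and -0.55 without edited library 1. For SOX2 it was -1.45 without control library 2. Neither passed with an interaction term.

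The wider pattern is that the 656 genes which fell in mouse morulae had a bovine median near 0 (0.02), although some genes and lists went the same way in both species: TEAD4 was lower in bovine too, AMOTL2 had a bovine value of -0.73, and 11 of 12 targets of YAP and TEAD proteins were lower (camera adjusted p = 0.00683, adjusted p = 0.104 with an estimated correlation). Spread and depth of the bovine libraries alone are argued against by the 213 genes that fell at least 2-fold in mouse. For 94.8% of them (202 genes) the bovine 95% interval excluded the mouse fold change. Mouse folds picked as large, however, lie somewhat too far from 0. The mouse fold change (n = 2 per group) was also taken without its standard error, so this share is not a test of the difference. CTGF counts among the 202 genes (bovine interval from -1.13, mouse -1.17), yet its species difference of 0.88 ± 0.54 did not pass. A response weakened in proportion to the TEAD4 transcript lost, 86.2% in mouse and 58.1% in bovine, predicted a bovine median of -0.50. The observed median was higher by 0.52, against a spread of 0.0613 over 100 randomly drawn splits of the bovine libraries. A response with a threshold, or remaining TEAD4 mRNA that encodes no working protein, was not tested. Species or stage cannot be told apart, since 0 species were sampled at more than 1 stage, and a biological difference between mouse and cattle stays among the open explanations.

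The bovine count of 1 gene was set against other splits of the 12 libraries into 6 and 6. Of 100 splits drawn from 462, 7 gave at least as many genes, the real one included, and the highest of the others gave 4, so that chance cannot be excluded for the count by itself. At an unadjusted p under 0.05 the real split gave 522 genes, the other splits a median of 352, and 29 of the 100 splits as many as the real one. The highest other split gave 1565, which points to a structure of the samples other than the groups.

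Of 64 groups of bovine values, 6 held a sample far from the others, each time the highest. About 3.2 (1 in 20) would arise by chance if values were normally distributed. Normalized reads were not put on a log scale, and some genes were chosen after their values were seen, so 3.2 is not a firm baseline. The gap to the nearest sample, as a share of the range of the group, was 0.713 for CYR61 in control library 1 (49.9 normalized reads, next 18.5) and 0.64 for CYR61 in edited library 1 (25.3, next 10.9). It was 0.688 for NANOG in control library 3 (172, next 53.6) and 0.751 for NANOG in edited library 3 (226, next 56.8). For PAG2, a pregnancy-associated glycoprotein gene, it was 0.858 in edited library 3 (139, next 26.1). The share of reads from the 18S ribosomal RNA gene in edited library 2 (19.7%, next 13.1%) gave 0.628. Samples were set only against their own group, so this flag does not mark the highest share. Control library 6 had 36.6%, with control library 3 next at 25.2%, and was not flagged. It also had the lowest mean correlation with the other bovine libraries (0.849).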

How the results depend on the processing

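The alternatives were planned, except scaling without the most abundant feature and removal of the length trend, which were chosen after seeing the data. The mouse count of 1742 genes lay between 1305 and 1887 in the fits with all libraries and between 580 (without control library 1) and 2588 (without edited library 2) when 1 library was left out; the cause was not tested. The bovine count was 1 in all fits but DESeq2, which gave 5, and the overlap of calls between species was 0 in all but DESeq2, which gave 1; the cause was not tested. With an estimated correlation 0 of 9 mouse lists and 0 of 6 bovine lists kept their call. In mouse, with 2 samples per group, that test has few degrees of freedom. Hardly any list could pass there, so a lost mouse call decides little. Leaving out 1 library gave 2 (without edited library 5) to 6 bovine lists, and 3 without control library 3. Core genes that differed between species were fewest, 6, with the interaction term and with a mean of at least 50. That filter left 12 core genes to test. The number was highest without mouse edited library 2. With the replicate block the counts were 1816 in mouse and 1 in bovine. The numbers were not taken to pair the samples. Deviations of same-numbered bovine samples correlated at -0.193 to 0.335, and only those of number 1 correlated best with each other. In both bovine groups, however, CYR61 was highest in number 1 and NANOG in number 3. With the number as a block the standard error of the NANOG species difference was 0.50, against 1.08 without. Some sharing by number thus cannot be excluded. In mouse, with 2 samples per group, deviations within a group mirror each other, so both pairs share 1 value (0.106), which cannot show pairing. Among other results, 2558 values kept direction and side of the threshold, 138 no longer passed, 21 newly passed, 8 counts by direction moved by over 1.5 times and 1 reversed. That was the bovine list of ribosomal proteins, whose median over the fits that left out 1 library ran from -0.12 (without control library 2) to -0.0026 (without edited library 4), where its set test pointed up, and was 0.04 with the same total per sample; the cause was not tested. Bovine depth limits low genes such as CDX2, which was below the filter. With no filter on low values 22 core genes were tested and 10 differed between species, CDX2 (1.89, adjusted p = 0.0165) and GATA4 (-2.77, adjusted p = 0.00149) among them.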

Other observations

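The gene families by name prefix, the matching on length and abundance, the length tests, the oocyte list test and the Xist test were chosen only after the results were seen, as was the use of the same total per sample and of leaving out an edited library, both fits fixed in advance, to test an explanation. The prediction for the sums over multicopy families was written before its result, but the sums were not among the tests fixed before the data were examined. Of 13 prefix families tried per species, the mitochondrial ribosomal protein genes fell in edited mouse morulae, 20 of 77 over all genes with 0 rising (limma), at a median of -0.43 (camera adjusted p = 7.76e-09, adjusted p = 0.647 with an estimated correlation, 0.000133 with the length trend removed). The proteasome genes (37 tested, 7 fell, median -0.22) and the clustered histone genes (18 tested, 4 fell, median -0.76) each had a camera adjusted p of 0.011, which was lost with the length trend removed (0.156 and 0.542) and with an estimated correlation (0.647 and 0.528). In bovine blastocysts no member passed with limma, and the medians lay the other way for the mitochondrial ribosomal genes (0.15, camera adjusted p = 4.65e-05) and the proteasome genes (0.21, 3.74e-06), each with adjusted p = 0.461 with an estimated correlation. The bovine histone genes had a median of -0.31 (camera adjusted p = 0.0285, 0.516 with an estimated correlation) and the vacuolar ATPase genes one of 0.19 (0.0319, and 0.461). Scaling to the same total put the median of all genes at 0.12 in mouse (0.17 without the most abundant feature) and 0.13 in bovine, closer to 0 than each of these medians of the same species.

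Other bovine genes looked at after their values were seen did not pass with limma. The trophoblast product PAG2 had a log2 fold change of -1.73 ± 0.70 and the prostaglandin synthase gene PTGES one of -1.12 ± 0.53, in the direction of mouse Ptges, and that of GNB4 was -0.90 ± 0.20. LOC101905194, which lies on chromosome 7 close to LOC101905257 in the assembly ARS-UCD2.0, near HAVCR2, had -1.21 ± 0.37, whereas TEAD4 lies on chromosome 5.

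Ribosomal protein and nuclear oxidative phosphorylation transcripts were lower in edited mouse morulae, as were short and abundant transcripts in general (Spearman across genes 0.171 with length, 0.164 with GC content, whose trend was not removed in any fit, and -0.141 with mean value), although between libraries of 1 group the correlation with length was of similar size, 0.146 for control 2 minus control 1 and -0.114 for edited 2 minus edited 1. The length of the longest annotated transcript is argued against as the whole cause, since the medians stayed at -0.28 and -0.32 with its trend removed. The expressed transcript can be shorter than the longest annotated one, so the expressed length was not tested and is not excluded. Both lists still passed with the trend removed at the preset correlation. Neither passes with an estimated correlation (adjusted p = 0.402 with all libraries). With the same total per sample the medians were -0.48 and -0.46, and both lists passed at the preset correlation too. That scaling moves nearly all genes of a sample alike, so a test of a list against other genes could hardly change. It shows only that the lists were low relative to other genes at either scaling. Against 20 genes outside both lists matched on length and mean value, ribosomal genes differed by -0.19 (95% interval over list members -0.24 to -0.14). That was less than 50% of their median of -0.60, so a fall shared with other short, abundant transcripts may be the larger part. The match was not exact, with median lengths of 1173 nucleotides in matched and 1054 in ribosomal genes and median values of 3630.5 and 4862.5 normalized reads. For oxidative phosphorylation the difference from matched genes was -0.25 (-0.31 to -0.18) and -0.32 with 10 matched genes, so whether the shared fall is the larger part cannot be told apart from a fall of its own, and this criterion was tightened after the values were seen. Both intervals come from resampling list members, which are not independent, and leave out the spread between samples. Whether the shared part comes from the RNA or from library making was not tested.

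Cleavage-stage transcripts were higher in edited mouse morulae. Reads shared unevenly between near-identical copies are argued against for the copies that have values here. In 2 of 3 multicopy families the summed normalized reads were higher in both edited than in both control libraries (Usp17l 223 and 408 against 4.47 and 8.85, Tdpoz 355 and 223 against 103 and 69.6). Zscan4 was the exception (7.63 and 85.1 against 17.9 and 1.26). The sums cannot recover reads lost to other copies or dropped for several matches, and the control sums of Usp17l rest on 4 and 7 reads. A single edited library is argued against too, as the list passed without either at the preset correlation (higher adjusted p = 9.67e-07), although not with an estimated correlation (adjusted p = 0.402 with all libraries). Edited embryos at an earlier stage remain possible, because the oocyte and maternal list, whose members went both ways, decides nothing (adjusted p = 0.892), a reading revised after that value was seen. A delay could therefore not be told apart from an effect of Tead4 loss on these transcripts, or from another effect of the guide RNAs, which the controls did not receive.

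Y-linked transcripts were higher in the edited mouse samples. Ddx3y stood at 51.4 and 91.1 normalized reads in control and at 245 and 155 in edited samples (281% of the control mean, adjusted p = 0.00142 from limma), and Eif2s3y (1.01 ± 0.27) and Kdm5d (2.23 ± 0.76, adjusted p = 0.0479) also passed, in fits with all libraries alone. A larger share of male embryos is a candidate explanation that stays open, since Xist, transcribed in female embryos, had a log2 fold change of -0.19 with a 95% interval from -0.58 to 0.19. Bovine XIST stood at 846, 1026 and 643 normalized reads in control libraries 2, 3 and 6 and at 0 to 20.8 in the other controls. In edited libraries 4 and 5 it stood at 515 and 298, and at 0 to 21.2 in the other edited libraries. Embryo sex was not part of any fit. Bovine NANOG ranged from 0 to 172 over control samples and from 0.648 to 226 over edited samples.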
